A study of Rattus norvegicus with 2 samples.

How the data were processed

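Gene expression was measured in whole-eye total RNA from 2 samples, 1 of HiSER and 1 of the SDR control, by one-colour hybridisation of Cy3-labelled cRNA to Agilent arrays. The labels assign each sample to its group through the phenotype field, and they do not say how many animals or eyes went into each RNA. The deposited values are linear intensity values per array feature, 1 column per sample, made with Agilent Feature Extraction 10.10 per the submitters' processing notes. Which output column of that program was taken, how the background was corrected and which array design was used are not given in the sources used here. The positive values, the dense lower edge in each array and the unequal quartiles of the arrays are those of signals that were not scaled between arrays. Rows carry only whole numbers from 1 to 420288. Control spots could not be told from other features and were kept, as were features that may be saturated.

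Each array was divided by its 75th percentile. Both arrays were then floored at the higher of their 2 scaled lower edges, -5.95 on the log2 scale, and log2 was taken. The lower edge was the gap above the lowest group of values in a histogram with log2 bins of 0.1. A feature counted as measured when at least 1 array was at or above its 50th percentile. Differences are HiSER minus control. Features at least 2-fold higher or lower were counted, as were features below the 25th percentile of one array and at or above the 75th of the other, taken before the floor. For any named feature below the 25th percentile of its dimmer array, the fold was bounded with that percentile in place of the value. With 1 array per group no test was run.

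The plan made before the data were examined was written for genes. It named the 12 largest differences in each direction, averaged the probes of a gene and used 26 lists of genes for lens, retina, cornea, pigmentation, inflammation, stress and other tissues. Because features could not be paired with genes, the counts and the rule for named items were applied to features, the 12 largest in each direction are summarised with the first 2 of each named, and the gene lists, the averaging of probes and its alternatives were not used. The bright features, with at least 32 times the 75th percentile in the array where they were brighter, were defined after the data were examined.

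Alternatives were median centring, quantile normalization, removal of a loess trend of difference on mean signal (fraction 0.2, 3 robust iterations, fitted on measured features), no filter or a filter at the 75th percentile, addition of each array's 25th percentile before log2, thresholds of 1.5-fold and 4-fold, and the 10th and 90th percentiles for features low in one array. Removal of the medians of tiles of 20 by 20 features, omission of the floor and a brightness limit of 8 times the 75th percentile were added after the data were examined. The row length of the array used for tiles, 398 features, was inferred from the lag at which differences were most alike. Their autocorrelation at this lag was 0.015, against at most 0.0069 in 100 shuffles of the features, and 398 divides the number of features into 1056 rows with a remainder of 0. The counting was tested on simulated data made from the 420288 control values, and all 50 features changed at each of 4 log2 sizes (2, -2, 4 and -4) were recovered. Only features with higher control signals were changed. The recovery therefore does not cover dim features or smaller changes, and it does not measure false calls. Calls among the unchanged simulated features were counted separately and are not given here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.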

Results

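Whole-eye RNA of the Hirosaki Small Eye Rat (HiSER), from white eye tissue with opacity, was compared with whole-eye RNA of the SDR control, whose eyes are red and whose genetic background HiSER shares. According to its title, the study sought the gene or genes behind the ocular abnormalities of HiSER. Each RNA was labelled with Cy3 and hybridised to 1 Agilent one-colour array of 420288 features, so each group had 1 array and no difference below has a replicate check or a p-value. Features are given by their number on the array, because no table pairing those numbers with probes or genes was used here, and neither genes nor genomic positions are named.

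The deposited signals were brighter overall in the HiSER array. The median feature signal was 207 in HiSER and 134 in the control, and the 75th percentile was 593 and 387, a ratio of 1.53. In HiSER 7.76% of features lay in a dense group of values at the lower edge of the signal range, below 4.76, and in the control 11.4% lay below 6.28. The brightest features reached 622742 in HiSER and 608420 in the control. The number of arrays, 1 per group, limits the precision of every value.

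Most features had similar signals in both eyes. After each array was scaled to its 75th percentile, 221072 features (52.6%) were measured, meaning that at least 1 array was at or above its median. The median log2 difference of these features, HiSER minus control, was 0.014, with a robust SD across features of 0.28, and 96.6% of them differed by less than 2-fold. Across measured features, which are not independent replicates, the log2 signals of the arrays had a Pearson correlation of 0.96 and a Spearman correlation of 0.95. Signal was more concentrated in the control, where the brightest 420 features held 19.9% of all deposited signal against 14.9% in HiSER. Both arrays reached like maximum signals although most HiSER signals were brighter, so a limit at the top of the range could contribute to this. Of these 420 brightest features, 354 were the same in both arrays.

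Of the measured features, 3156 (1.43%) were at least 2-fold higher in HiSER and 4294 (1.94%) were at least 2-fold lower. At 4-fold, 775 features were higher and 1089 were lower, and at 16-fold 120 were higher and 259 were lower. Lower features made up 57.6% of the 2-fold differences, but only 47.6% (3668 lower, 4042 higher) once a loess trend of difference on signal was removed. That correction raised the median difference over all features, dim ones included, by 0.24 on the log2 scale. Features dimmer than the fitted range were given the trend's value at its dim end. The median of the measured features was 0.014 before the correction and 0.017 after it. Measured features were chosen again after the correction. The later median and counts can therefore cover partly other features than those on which the trend was fitted. When the measured features were divided by mean signal into 10 groups of equal size, the dimmest group held 1283 of the higher and 1745 of the lower features and had a robust SD of 0.51, against 0.25 in the 2 middle groups. The filter can widen the spread in the dimmest group, because a feature below the median of one array was measured only if the other array reached its median. In the brightest group 117 features were higher and 430 were lower.

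The difference was most uneven among the brightest features. In the control array 5133 features had at least 32 times the 75th percentile, and 223 of them (4.34%) were at least 2-fold lower in HiSER. In the HiSER array 4545 features were this bright, and 20 of them (0.44%) were at least 2-fold higher than in the control. The split was 227 lower and 20 higher with median centring, and less uneven under the other scalings, with 161 lower and 38 higher after quantile normalization and 163 lower and 31 higher with the loess trend removed. At 4-fold, 106 bright features were lower and 0 were higher, and the largest excess of a bright HiSER feature was 3.53-fold. At 32-fold, 17 bright features were lower, and at 256-fold 10 were lower. This brightness limit was chosen after the data were examined, and the absence of higher features from 4-fold on depends on it. From 8 times the 75th percentile, 179 features were at least 4-fold lower and 35 at least 4-fold higher. The largest excess in HiSER was then 51.7-fold.

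**Figure D1:**
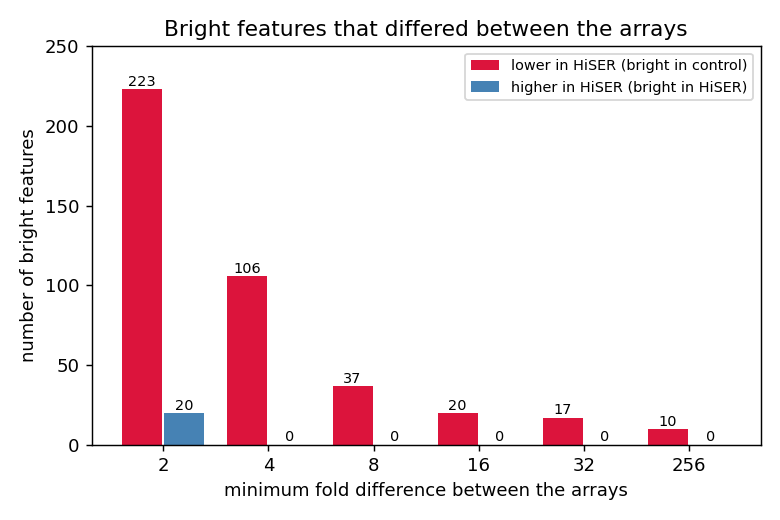
Number of bright features (y axis) that differed between the arrays by at least the fold on the x axis; features bright in the control (at least 32 times its 75th percentile) were counted when lower in HiSER, and features bright in HiSER when higher there. Lower features fell from 223 at 2-fold to 10 at 256-fold, while higher features numbered 20 at 2-fold and 0 from 4-fold on. With a limit of 8 times the 75th percentile, not drawn, 35 features were at least 4-fold higher and 179 at least 4-fold lower.

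The 10 features at least 256-fold lower in HiSER were separated from the rest. Of these, 7 had control signals from 384012 to 521614, ranking from 16 to 54 among all control features, and HiSER signals from 14.2 to 582. The other 3 had control signals from 31563 to 92655 and HiSER signals from 3.30 to 36.0. Of the 10, 5 lay below the HiSER array's 25th percentile of 54.8, so that their difference is only bounded. Another 7 bright features were lower by 32-fold to 256-fold, with control signals from 21504 to 334792 and HiSER signals from 308 to 6949. The 10 brightest features of the HiSER array had almost equal deposited signals in the control, with a median log2 difference of 0.026, which became -0.59 after scaling. Near the top of the range, scaling thus moved almost equal deposited signals towards lower values in HiSER. Differences that involve such signals are therefore imprecise and shifted in that direction, which can add to the count of lower bright features.

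**Figure D2:**
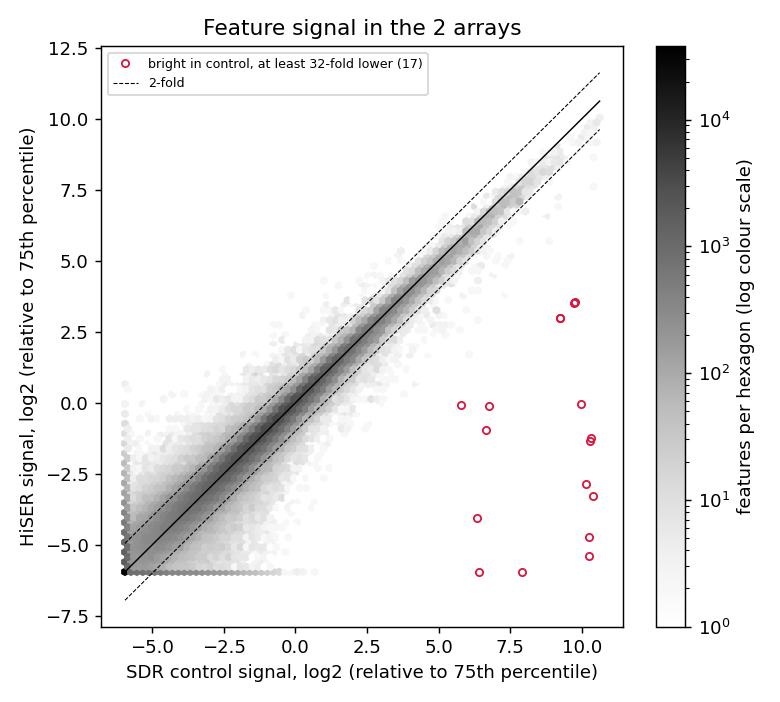
Scaled log2 signal of each feature in the control (x axis) and in HiSER (y axis), both relative to the array's 75th percentile; grey hexagons show the number of features, the solid line equality and the dashed lines 2-fold differences. The 17 circled features, bright in the control and at least 32-fold lower in HiSER, lie apart from the main cloud. No feature at least 32 times the 75th percentile in HiSER lies at the mirrored position. With a limit of 8 times the 75th percentile, 2 features were at least 32-fold higher in HiSER and 19 at least 32-fold lower.

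The 12 largest differences in each direction involved signals below the 25th percentile of the dimmer array in 6 of the 12 lower and all 12 of the higher features. These features were ranked on the scaled values before any bound, so background signal influenced their choice, and their sizes are given with neither array set below that percentile. For the 12 lower features chosen in this way the bounded log2 differences ranged from -13.70 to -5.07, and 11 of them were among the bright control features. For the 12 higher features they ranged from 3.75 to 6.35, with HiSER signals from 741 to 4507, and 0 of the 12 were among the bright HiSER features. Feature 352294 had a signal of 470713 in the control and 14.2 in HiSER, which makes it at least 13160-fold lower when the HiSER value is replaced by the 25th percentile of its array. Feature 195048 had 474512 in the control and 22.5 in HiSER, at least 13266-fold lower by the same bound. In the other direction, feature 117984 had 1315 in HiSER and 4.68 in the control, at least 23.9-fold higher, and feature 355362 had 4353 in HiSER and 21.3 in the control, at least 79.0-fold higher.

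A total of 37 features were below the 25th percentile in HiSER and at or above the 75th percentile in the control, and 30 features showed the opposite. This balance turned to 43 and 46 with the loess trend removed, and with the 10th and 90th percentiles the counts were 3 and 0. The bounded fold had a median of 15.8 for the 37 features low in HiSER and 14.0 for the 30 low in the control. Of the 37, 5 reached at least 32 times the 75th percentile in the control, and 0 of the 30 did so in HiSER. The largest bound was 13266-fold for a feature low in HiSER and 81.8-fold for a feature low in the control.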

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

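For the features at least 2-fold higher and lower (3156 and 4294), the counts moved by over 1.5 times only with the threshold or the filter, to 8612 and 14508 at 1.5-fold, 775 and 1089 at 4-fold, 14126 and 14426 with no filter, and 1389 and 1914 with the filter at the 75th percentile. With the 10th and 90th percentiles, 3 features were low only in HiSER and 0 only in the control; with the loess trend removed, 43 were low only in HiSER and 46 only in the control, which turned the balance of 37 and 30. The bright features were examined under settings chosen after the data were seen. Against 223 lower and 20 higher, the counts were 106 and 0 at 4-fold and 510 and 171 from 8 times the 75th percentile, while 31 were higher with the loess trend removed (163 lower) and 38 with quantile normalization (161 lower). The cause of the last 2 shifts was not tested. The number of bright features at least 32-fold lower stayed at 17 under 6 alternatives and was 19 from 8 times the 75th percentile, where 2 were at least 32-fold higher. The 4 named features kept their direction under 6 alternatives each; their sizes are bounds and are not compared. Differences of dim features varied more, with a robust SD across features of 0.51 in the dimmest of 10 groups. The filter can add to this spread, so dim signal alone is not shown to cause it. Alternatives for several probes of a gene and for gene lists were not run, since features were not paired with genes, and no replicate could be left out.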

Other observations

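The tests of blemishes were chosen after the results were seen, that of array position was added after a first correction for position had moved little, and that of near-equal pairs after the pairs had been noticed in other features. In the 17 features bright in the control and at least 32-fold lower in HiSER, the log2 differences were -5.87 or below. Under 3 other scalings the smallest absolute difference was 5.71, so the choice among these scalings mattered little. Because the 17 were selected for large differences, this scaling test could hardly have come out otherwise. A blemish covering several features is argued against, as far as the inferred layout holds, by 37 measured features adjacent to the 17, whose median log2 difference was -0.0043 (95% bootstrap interval -0.077 to 0.096). That layout rests on an autocorrelation of only 0.015, though one above the highest of 100 shuffles, 0.0069; the 20 measured features next to them by number alone had a median of 0.028. Blemishes that dim single HiSER features by a like fold whatever their brightness are argued against by how often such drops occurred. The 17 were 0.33% of the 5133 features from 32 times the 75th percentile in the control. From 8 times, a limit that includes those 5133, 19 of 17011 features (0.11%) were at least 32-fold lower. Other blemishes covering single features, including any in the control array, stay open. Of the 17, 8 had a partner within 0.5 log2 in both arrays, fewer than the 95th percentile of 9 over 10000 shuffles of the differences. Control spots among the 17, variation between animals and a difference due to the HiSER genotype also stay open; none was tested, with 1 array per group and features not paired with probes.

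Among features bright in their own array, 223 were at least 2-fold lower in HiSER and 20 higher. With the signal-dependent trend removed, 163 were lower and 31 higher, a ratio of 5.26. The ratio was 8.35 (167 lower, 20 higher) among bright features under 256 times the 75th percentile, where a signal ceiling acts least. Position on the array was tested by dividing the inferred layout into 10 bands of rows and 10 of columns: lower bright features numbered over 2 times the higher ones in 20 of these 20 parts, with 13 to 31 lower and 0 to 5 higher in each. Every feature falls in both a row band and a column band, so the 20 parts are not independent. The bright sets came from the main scaling throughout, so any effect of a trend or ceiling on which features counted as bright was kept. Within these sets, the values argue against a trend, a ceiling or a position effect, each taken alone, as the whole cause. Their joint effect was not tested. The HiSER genotype and a difference in RNA quality or labelling between these 2 samples were not tested and remain open.

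Bright features with large differences were noticed to come in near-equal pairs: of 54 features with at least 8 times the 75th percentile in the control and at least 8-fold lower in HiSER, 31 had a partner within 0.15 log2 in both arrays. Because these features prompted the idea, several spots of one probe was tested on the other 456 features of this brightness that were 2-fold to under 8-fold lower. Of these, 295 had a partner within 0.05 log2 in both arrays, against a median of 257 and a maximum of 285 in 1000 shuffles of the differences within blocks of 10 features of like control signal. The excess is modest, and probes of one transcript with like signals would also give it. If either holds, the counts of features may exceed the number of distinct transcripts that differ.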
